A study of Mus musculus with 6 samples.

How the data were processed

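RNA of 6 mouse samples had been hybridised to Affymetrix mouse expression arrays, 4 from MIN6 cells, a mouse beta-cell line that secretes insulin, and 2 from pancreatic islets. The MIN6 cells carried an adenovirus for green fluorescent protein (AdGFP, 1 array), for miR-7a (AdmiR7a, 2 arrays) or for miR-7b (AdmiR7b, 1 array), at a multiplicity of infection of 250 for 48 h in medium with 4.5 g/l glucose and 2% serum. The islets came from mice lacking miR-7a2 in beta cells (KO, 1 array) and from wild-type mice (WT, 1 array). Groups were taken from the sample labels alone.

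The deposited values are log2 probe set intensities that the authors made with GCRMA, which corrects the background from probe sequence and quantile-normalizes the arrays; the submitters' processing notes name GCRMA and the affy package without versions. The upper quartile of all probe sets lay between 7.95 and 8.01 on the 6 arrays, and the median between 2.98 and 3.01 on the MIN6 arrays, 3.33 in KO and 3.29 in WT islets. Whether other arrays were normalized with them is not stated. The scanner files were not used. The table held 45101 probe sets, of which 34958 carried 1 gene symbol, 932 several and 9211 none in the gene table used here; 64 were control probe sets. The Entrez identifiers of 34754 probe sets were found in the RefSeq gene table (assembly GRCm38.p6), which served only for names, older symbols and gene order. Each of the 18194 genes was given the value of its probe set with the highest mean over the arrays of the system, MIN6 or islets. Genes with a mean below 4 (log2) were left out, which left 10369 genes in MIN6, 10568 in islets and 9781 in both. Some members of the gene lists, such as Mafa and Ins1, had no named probe set in the table and were not analysed here. Mature miR-7 was not measured.

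Design, filter, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The AdmiR7a arrays were compared with AdGFP by limma 3.58.1 (R 4.3.3), with a mean per vector and 1 residual degree of freedom. Because miR-7a and miR-7b share their seed, the 3 arrays with either vector were also pooled against AdGFP, with 2 residual degrees of freedom; "rose" and "fell" refer to this pooled fit, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Both fits assume that the lone AdGFP array varies like the miR-7 arrays. The series describes AdmiR7a as a duplicate infection but not whether the cultures were separate, so the spread behind the SEs and adjusted p may leave out variation between cultures. AdmiR7b was tested against AdmiR7a in the fit with a mean per vector. AdmiR7b against AdGFP and KO against WT islets had 1 array per group, so genes were counted there by a log2 difference of at least 1, with no replicate check and no p-value for these counts; a limma contrast of AdmiR7b that borrows the spread of the AdmiR7a arrays was an alternative. The pooled fit was tested on simulated data with 200 changed genes: it recovered 4% of changes of 0.58 (log2), 58% of 1, 88% of 2 and 96% of 3, with 4 false calls. The fit on AdmiR7a recovered 0% at each of these sizes. These shares hold for 200 changed genes and depend on that number. The simulated AdGFP array varied like the miR-7 arrays, so false calls from a deviation of the real one are not covered.

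Gene lists (23) were described by the members that passed the test, over all genes and adjusted over the list alone, and by the median log2 difference with its percentile among 10000 random lists of the same size matched on expression in 20 bins. Of 400 random null lists, 5.5% fell outside the central 95%. These were drawn at random from the same genes, so the check does not cover lists whose members move together. Lists with at least 3 measured members in MIN6 (18 lists) were tested in the pooled fit with camera and with fry. Camera was run at its preset correlation of 0.01 and at an estimated correlation. The estimate was -0.044 for miR-7 targets from other systems and -0.016 for insulin and mTOR genes. For these lists, members that move together are thus not why the second camera run gave weaker results. That run takes its p from the 2 residual degrees of freedom of the pooled fit. This raises p even where members do not move together. The correlation of the AdmiR7a and AdmiR7b differences across genes was set beside 100 simulations of unchanged groups that share 1 AdGFP array. Differences in MIN6 and in islets were compared by Pearson's r and Spearman's rho across genes and by counts at a log2 size of 0.58 and 1, beside the number 2 independent sets would share.

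Named genes were the 10 highest and 10 lowest with AdmiR7a among genes past a log2 size of 1 in both arrays, the 5 highest and 5 lowest with AdmiR7b, the 10 highest and 10 lowest in KO islets, up to 10 genes low with miR-7 and high in KO and up to 5 of the opposite, always with the higher group at 6 or more. From each list they were all 8 members the study reported as targets, or otherwise up to 4 members with the largest difference and the hallmark members written first. Genes without a single symbol or with predicted names were passed over. Alternatives were no filter and a filter at 6, renormalization, centring, the mean of all probe sets of a gene, each probe set on its own, a trended robust prior, other thresholds and leaving out each miR-7 array. The planned comparison of genes with and without miR-7 seed sites was not run, since no 3' UTR sequences were at hand. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). The number of arrays limits the precision of every value.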

Results

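The series holds 6 arrays: 1 of MIN6 cells with AdGFP, 2 with AdmiR7a, 1 with AdmiR7b, 1 of islets lacking miR-7a2 in beta cells and 1 of wild-type islets. Between 44.7% and 45.0% of probe sets lay above a log2 value of 4 on each MIN6 array, against 46.4% in KO and 46.2% in WT islets. The 2 AdmiR7a arrays differed by an SD of 0.194 (log2) across genes and the AdmiR7b array from them by 0.215 and 0.207. The AdGFP array differed from the AdmiR7a arrays by 0.511 and 0.509 and from the AdmiR7b array by 0.575.

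Raising miR-7a in MIN6 cells asks which transcripts of a beta cell respond to the microRNA. The genes highest with AdmiR7a were Defb1, an antimicrobial beta-defensin, 22.7-fold above AdGFP, and Plet1, 13.4-fold above it. The lowest were the cytokine gene Il4 (-3.33, log2), the protease gene Ctsk, 9.52-fold below, and Tacr3, the neurokinin B receptor, 8.34-fold below. With the 3 miR-7 arrays pooled against the 1 AdGFP array, Defb1 rose by 4.46 ± 0.17 (log2, SE; adjusted p = 0.010) and Plet1 by 3.84 ± 0.24 (adjusted p = 0.0109). Il4 fell by 3.33 ± 0.07, Ctsk fell by 3.26 ± 0.08 and Tacr3 fell by 3.13 ± 0.39 (adjusted p = 0.00886, 0.00886 and 0.0179).

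Among the other highest genes, Klhdc8b rose by 3.04, the p53 target Plk2 by 2.97, Lrrc39 by 2.84, the syndecan gene Sdc4 by 2.79, the organic anion transporter gene Slco1a6 by 2.73, the prostaglandin D synthase gene Hpgds by 2.52, the antiviral gene Rsad2 by 2.48 and the kinesin light chain gene Klc3 by 2.47. Among the other lowest genes, Tcim fell by 2.63, the cholecystokinin receptor gene Cckar fell by 2.54, the lysine-degrading enzyme gene Aass fell by 2.54, the heat shock gene Hspa1a fell by 2.39, the cystathionine gamma-lyase gene Cth fell by 2.34, Hhat fell by 2.26 and the purinergic receptor gene P2ry1 fell by 2.21. The adjusted p of these 15 genes in the pooled fit lay between 0.010 and 0.0253. On AdGFP, Defb1 (2.57), Plet1 (2.38), Lrrc39 (3.68) and Sdc4 (3.59) were below the level of 4 used as filter. Klhdc8b (4.10) and Plk2 (4.11) lay just above that level. Of the p53 targets counted below, Phlda3 (4.11) also lay just above it and Eda2r (2.88) under it. The folds of all these genes depend on values near the background. Il4 was below it on the miR-7 arrays (3.82 on average with AdmiR7a, 3.81 with AdmiR7b), so its difference and small SE are limited by the background.

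**Figure D1:**
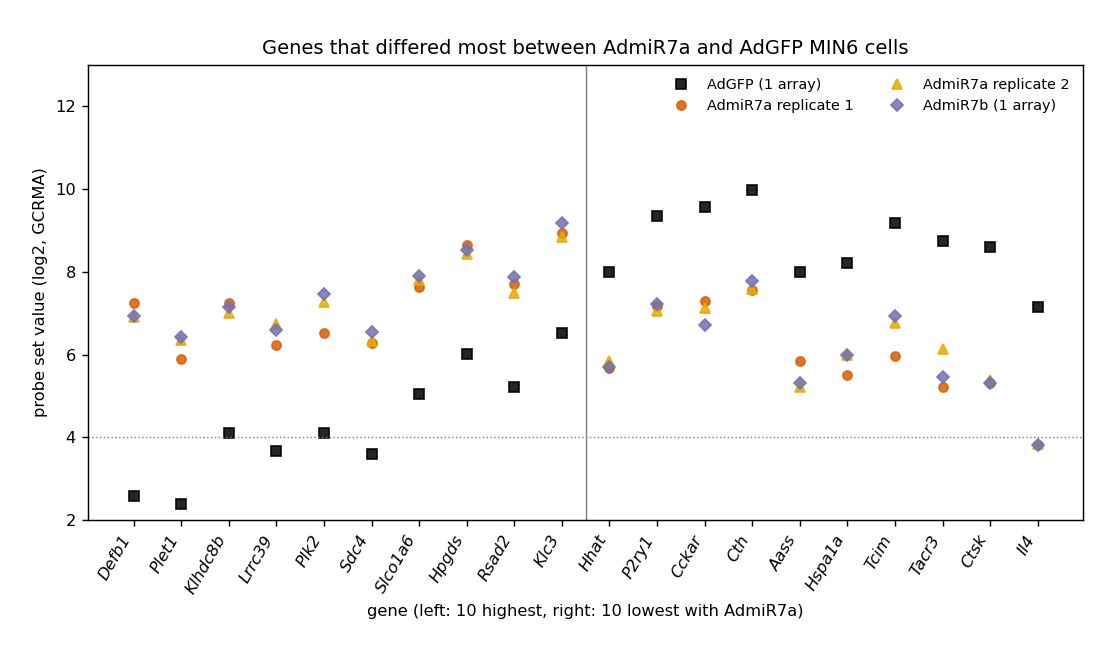
Probe set values (log2, vertical axis) on each of the 4 MIN6 arrays for the 10 genes highest and the 10 lowest with AdmiR7a against AdGFP; each point is 1 array and the dotted line marks the filter at 4. For all 20 genes the 3 miR-7 arrays lie on the same side of the AdGFP array.

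All 6 measured genes that the study reported as miR-7 targets fell. Cplx1, which encodes the fusion clamp complexin 1, fell by 2.00 ± 0.18, the palmitoyltransferase gene Zdhhc9 fell by 1.61 ± 0.14 and the actin and phosphatase regulator gene Phactr1 fell by 1.23 ± 0.11. Dnajc5, a vesicle chaperone gene, fell by 0.93, the actin regulator gene Wipf2 fell by 0.86 and the profilin gene Pfn2 fell by 0.83. All 6 also fell adjusted over the list alone; the study chose this list, so its direction is not independent evidence. The list's median was -1.08, with camera adjusted p = 0.000124 and adjusted p = 0.423 with an estimated correlation.

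Of 17 measured miR-7 targets described in other systems, 9 fell and 1 rose, over all genes as adjusted over the list alone. Parp1, which encodes the DNA repair enzyme, fell by 1.56 ± 0.20, the IGF1 receptor gene Igf1r fell by 1.34 ± 0.13 and the MAP kinase-interacting kinase gene Mknk1 fell by 1.12 ± 0.10. The receptor gene Egfr (-0.45, adjusted p = 0.219) and Klf4 (-0.12, adjusted p = 0.622) did not pass. The list's median was -0.57, at the 0.01 percentile of random lists, with camera adjusted p = 0.00752 and adjusted p = 0.423 with an estimated correlation.

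Beta-cell transcription factor genes were lower as a group: of 13 measured, 8 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. Mnx1 fell by 1.05 ± 0.11, Pax6 fell by 1.0 ± 0.15, Pdx1 fell by 0.99 ± 0.10, Foxa2 fell by 0.89, Glis3 fell by 0.85 and Nkx6-1 fell by 0.76, whereas Hnf4a rose by 0.68 ± 0.12. Insm1 stood at -0.95 ± 0.30 (adjusted p = 0.0879). The median was -0.76 (camera adjusted p = 0.000304, and adjusted p = 0.423 with an estimated correlation).

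Of 22 genes of insulin production, glucose sensing and granules, 7 fell and 0 rose, with the same counts adjusted over the list alone. Ero1b, which serves insulin folding, fell by 1.30 ± 0.13, the urocortin gene Ucn3 fell by 1.15 ± 0.08, the potassium channel subunit gene Abcc8 fell by 0.82 ± 0.09, the cation channel gene Trpm5 fell by 0.79 and Ppp1r1a fell by 0.72. The insulin gene Ins2 stood at 0.06 ± 0.12 (adjusted p = 0.723) at a level near the top of the scale, 15.8 on AdGFP. The list's median was -0.19, with camera adjusted p = 0.000168 and adjusted p = 0.423 with an estimated correlation.

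**Figure D2:**
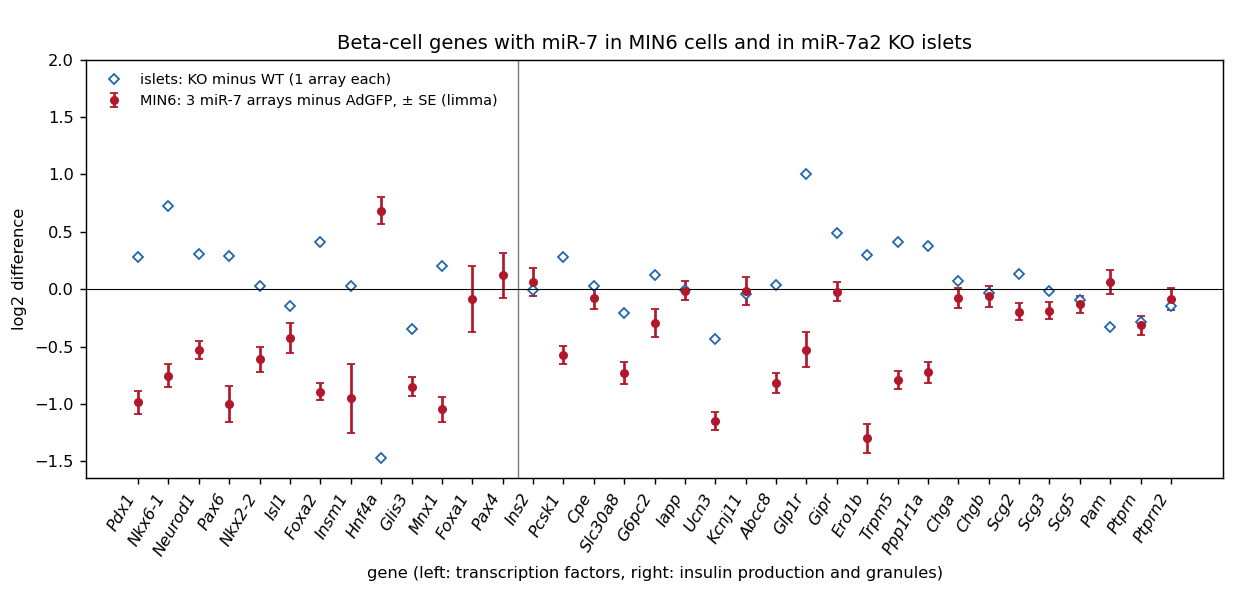
Log2 differences of beta-cell transcription factor genes (left of the line) and of genes for insulin production and granules (right), as the 3 miR-7 arrays minus 1 AdGFP array in MIN6 (filled, bars are the limma SE) and as KO minus WT islets (open, 1 array each). Pdx1 is at -0.99 in MIN6 and 0.28 in islets, and Hnf4a at 0.68 and -1.47.

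Insulin and mTOR signalling genes included 7 of 18 that fell and 2 that rose, as adjusted over the list alone. Besides Igf1r and Mknk1, Mknk2 fell by 0.89, the kinase gene Mtor fell by 0.81 and Akt2 fell by 0.67. The insulin receptor substrate genes Irs2 and Irs1 fell by 0.75 and fell by 0.67. Mapkap1 rose by 0.71, and Tsc1, an inhibitor of mTOR, rose by 0.36. Igf1r, Mknk1, Mknk2, Irs2, Irs1 and Mapkap1 are also in the list of miR-7 targets from other systems, so this result largely repeats that one. The median was -0.20 (camera adjusted p = 0.0173, and adjusted p = 0.423 with an estimated correlation). Of 23 exocytosis genes 5 fell and 3 rose (9 and 4 adjusted over the list alone), with a median of -0.11 at the 1.6 percentile of random lists and camera adjusted p = 0.213. Besides Cplx1 and Dnajc5, Cplx2 fell by 0.72, whereas the SNARE gene Stx1a rose by 0.84; Snap25 was at 0.22 (adjusted p = 0.119). Of 21 actin regulator genes 3 fell and 4 rose (4 and 5 adjusted over the list alone, camera adjusted p = 0.657). The gelsolin gene Gsn rose by 1.09 and Cfl2 rose by 0.36. The 3 that fell were Pfn2, Wipf2 and Phactr1, all in the study's list of targets, so they repeat that result.

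Of 14 measured genes that p53 induces, 6 rose and 1 fell, and adjusted over the list alone 8 rose and 1 fell. Besides Plk2, Phlda3 rose by 2.41 ± 0.29, Trp53inp1 rose by 2.09 ± 0.11 and Mdm2 rose by 1.03 ± 0.19; Cdkn1a, the cell cycle inhibitor p21, stood at 0.93 ± 0.25 (adjusted p = 0.0654), and Zmat3 fell by 1.17 ± 0.11. The median was 0.70, with camera adjusted p = 0.0173 (0.0532 without AdmiR7a replicate 2) and adjusted p = 0.591 with an estimated correlation; fry gave adjusted p = 0.0699. Of 5 measured interferon-induced genes, Rsad2, Irf9 (rose by 0.93) and Usp18 (rose by 0.87) rose, and 3 rose adjusted over the list alone (median 0.87, percentile 99.6; camera adjusted p = 0.0507). Of 13 cholesterol synthesis genes 4 rose, among them Fdft1 by 0.55, Dhcr7 by 0.46 and Idi1 by 0.43, and 8 rose adjusted over the list alone (median 0.27, percentile 97.6; camera adjusted p = 0.0564). Of 18 genes of the endoplasmic reticulum stress response, Atf3 rose by 2.11 and Ddit3 by 1.21, while Chac1 fell by 0.51 and Asns fell by 0.46, with the same counts adjusted over the list alone (camera adjusted p = 0.244). The list's median was -0.08, at the 2.35 percentile, and fry gave the opposite direction, up (adjusted p = 0.148).

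Among 25 cell cycle genes Rrm2 fell by 0.60 (0 calls adjusted over the list alone; camera adjusted p = 0.336), and the proliferation marker gene Mki67 was at -0.36 (adjusted p = 0.119). Of 14 genes normally kept low in beta cells, Cxcl12 fell by 1.22 and Ldha fell by 0.82 besides Zdhhc9, while C1qbp rose by 0.59 (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.336). Of 4 progenitor-associated genes Hes1 rose by 0.73 and Myc by 0.60 (2 rose adjusted over the list alone; median 0.44, percentile 97.6; camera adjusted p = 0.244). Of 10 glycolysis genes Ldha fell (0 adjusted over the list alone; camera adjusted p = 0.278).

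In the pooled limma fit 1480 genes rose and 1235 fell of 10369 tested, and 430 of them were past a log2 size of 1 in the same direction on all 3 miR-7 arrays (220 higher, 210 lower). The AdmiR7a arrays alone gave 0 genes by limma, with 3811 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0667, and the same fit called 0% of simulated changes. That 0 became 1737 with a filter at 6, 2362 with renormalization, 2325 with centring, 967 with averaged probe sets and 350 with no filter. The simulation behind the 0% changed 200 genes only, so that share does not carry over to data in which more genes differ. By size, 229 genes were higher and 223 lower in both arrays. Leaving out AdmiR7a replicate 1, AdmiR7a replicate 2 or the AdmiR7b array each left 0 genes in the pooled fit, with lowest adjusted p of 0.0650, 0.0772 and 0.0667. Every MIN6 difference rests on 1 AdGFP array, and the hybridisation controls were 0.188 (log2) higher on the miR-7 arrays on average and 18S ribosomal RNA stood at 14.0 on AdGFP against 13.6, 13.6 and 13.9, so any feature of that array enters all of them alike.

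The AdmiR7b array asks whether the other miR-7 sequence has the same effect. Highest with AdmiR7b were Defb1 (4.37), Plet1 (4.04), the stathmin gene Stmn4 (3.77), Plk2 (3.36) and the kinase gene Mapkapk3 (3.13). Lowest were Il4 (-3.34), Ctsk (-3.29), Tacr3 (-3.28), Cckar (-2.87) and Aass (-2.67). Of the genes past a log2 size of 1, 400 were higher and 442 lower with AdmiR7b than with AdGFP. Medians with AdmiR7b and with AdmiR7a, which share the AdGFP array, were -0.84 against -0.71 for beta-cell transcription factors, -0.64 against -0.56 for miR-7 targets from other systems, 0.84 against 0.62 for p53 targets, and 0.02 against -0.13 for genes normally kept low in beta cells. Stmn4 (2.90) and Mapkapk3 (3.44) were below 4 on AdGFP. With 1 array per group there was no replicate check, and the counts by size carry no p-value. A limma contrast that borrows the spread of the AdmiR7a arrays called 0 genes, with 3915 at an unadjusted p under 0.05.

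Between the vectors, limma called 0 genes for AdmiR7b minus AdmiR7a, with 608 at an unadjusted p under 0.05 and a lowest adjusted p of 0.737, in a fit that called 0% of simulated changes for AdmiR7a against AdGFP. That simulation changed 200 genes only. Of the 229 genes higher with AdmiR7a by size, 223 were also among the 400 higher with AdmiR7b. Of the 223 lower genes, 211 were among the 442 lower. Both sets use the same AdGFP array, and no overlap for unchanged groups was computed. No gene was past that size in opposite directions (0 genes). Across 10369 genes, which are not independent replicates, Pearson's r between the vectors' differences was 0.949 and Spearman's rho 0.928. In simulated unchanged groups that share 1 AdGFP array, r was 0.577 and rho 0.543. The covariance was 0.273 against a simulated 0.0105. The simulated AdGFP array varied only like the AdmiR7a pair, which differed by an SD of 0.194. The real AdGFP array differed from the miR-7 arrays by 0.509 to 0.575. A deviation of that array alone could raise r and the covariance, so the simulation cannot separate it from an effect of miR-7.

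Deleting miR-7a2 in beta cells is a change in the opposite direction, in the intact tissue. How much miR-7 remained in these islets was not measured. The gene highest in KO over WT islets was Mx1, an interferon-induced antiviral gene, 59.1-fold higher in KO, followed by Fam107a (14.9-fold), the fibrinogen gene Fgg (13.7-fold), the synaptic pentraxin gene Nptx2 (12.1-fold) and Star (11.3-fold), which delivers cholesterol for steroid synthesis. The neuropeptide gene Npy was 7.87-fold higher in KO, Nnat 7.10-fold and Tacr3 5.61-fold. Lowest was Reln, the gene of the matrix protein reelin, 35.9-fold lower in KO. On WT, Mx1 (2.54), Fam107a (3.01), Fgg (2.41) and Gipc2 (3.92) were below 4, near the background, and so were Reln (3.49), Bspry (3.41), Prr5l (3.40) and Rhbdl3 (3.79) in KO, so their differences are limited by it.

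Calml4 and Gipc2 were also higher in KO, by 2.63 and 2.53 (log2). Among the genes lower in KO were Bspry (-2.76), Prr5l (-2.61), Rhbdl3 (-2.54), the melanin synthesis gene Dct (-2.45), the peptide transporter gene Slc15a2 (-2.03), Uba7 (-2.02), Dcdc2a (-1.99), Rnf138rt1 (-1.99) and the complement gene C8b (-1.97). In all, 144 genes were at least 1 (log2) higher and 136 lower in KO than in WT islets.

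All 7 measured genes the study reported as targets were higher in KO, with a median of 0.44 at the 99.98 percentile of random lists; the list is the study's own and not independent evidence. Zdhhc9 was 0.70 higher, the membrane protein gene Basp1 0.51, Pfn2 0.46, Phactr1 0.44, Cplx1 0.33, Dnajc5 0.13 and Wipf2 0.12. Of 17 targets from other systems, 14 were higher and 3 lower in KO, with a median of 0.29 above all random lists (percentile 100). Igf1r was 0.83 higher, Klf4 0.64, Egfr 0.53, Mknk1 0.46, Irs2 0.43 and Parp1 0.41.

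Of 11 beta-cell transcription factor genes 8 were higher and 3 lower in KO (median 0.21, percentile 99.9). Nkx6-1 was 0.73 higher, Foxa2 0.41, Pax6 0.29 and Pdx1 0.28, whereas Hnf4a was 1.47 lower in KO (KO minus WT -1.47). The other lower genes were Glis3 (-0.35), which also fell in MIN6, and Isl1 (-0.15). Of 23 genes of insulin production and granules 12 were higher and 11 lower (median 0.02); the receptor gene Glp1r was 1.0 higher, Ucn3 stood at -0.43 and Ins2 at -0.01. Of 16 interferon-induced genes 14 were higher in KO (median 0.39, percentile 100), with Mx1, the chemokine gene Cxcl10 (1.32), Oas1a (0.77) and Rsad2 (0.76) among them. Of 14 p53 targets 11 were higher (median 0.34, percentile 100), including Cdkn1a (1.15), Perp (1.05) and Zmat3 (1.04), while Pmaip1 stood at -0.97. Medians of exocytosis (0.04, 24 genes), actin regulator (0.07, 22), insulin and mTOR (0.04, 18), endoplasmic reticulum stress (0.06, 18), cell cycle (-0.01, 14), cholesterol (-0.05, 13), glycolysis (-0.07, 10), disallowed (-0.06, 16) and progenitor (0.16, 4) genes lay within the central 95% of random lists. In exocytosis, Cadps2 was lower in KO (-1.22).

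Other islet cells differed little at the level of whole lists: medians were -0.02 for 5 alpha-cell genes, 0.03 for 5 delta, PP and epsilon genes, -0.05 for 3 ductal, -0.12 for 9 endothelial, 0.04 for 11 immune and -0.16 for 5 stellate genes. The hormone genes Gcg (-0.09), Sst (-0.03), Ppy (0.10) and Pyy (-0.09) differed by at most 0.10, at levels near the top of the scale, and Pecam1, an endothelial gene, was at -1.11. Spiked poly-A control transcripts were 1.31 lower in KO (KO minus WT -1.31) and 18S ribosomal RNA 0.33 higher. The 3' minus 5' difference of the actin control probe sets was 2.65 in KO and 2.77 in WT, and that of Gapdh 0.83 and 0.68. On the MIN6 arrays these differences were at most 1.48 and 0.05, so RNA quality may differ between the systems. With 1 array per group there was no replicate check and no p-value for any islet gene. When each gene took the mean of its probe sets, 183 genes were past the size in place of 280. The count was 134 with a filter at 6 and 423 with no filter. Over single probe sets, 573 were higher and 221 lower.

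**Figure D3:**
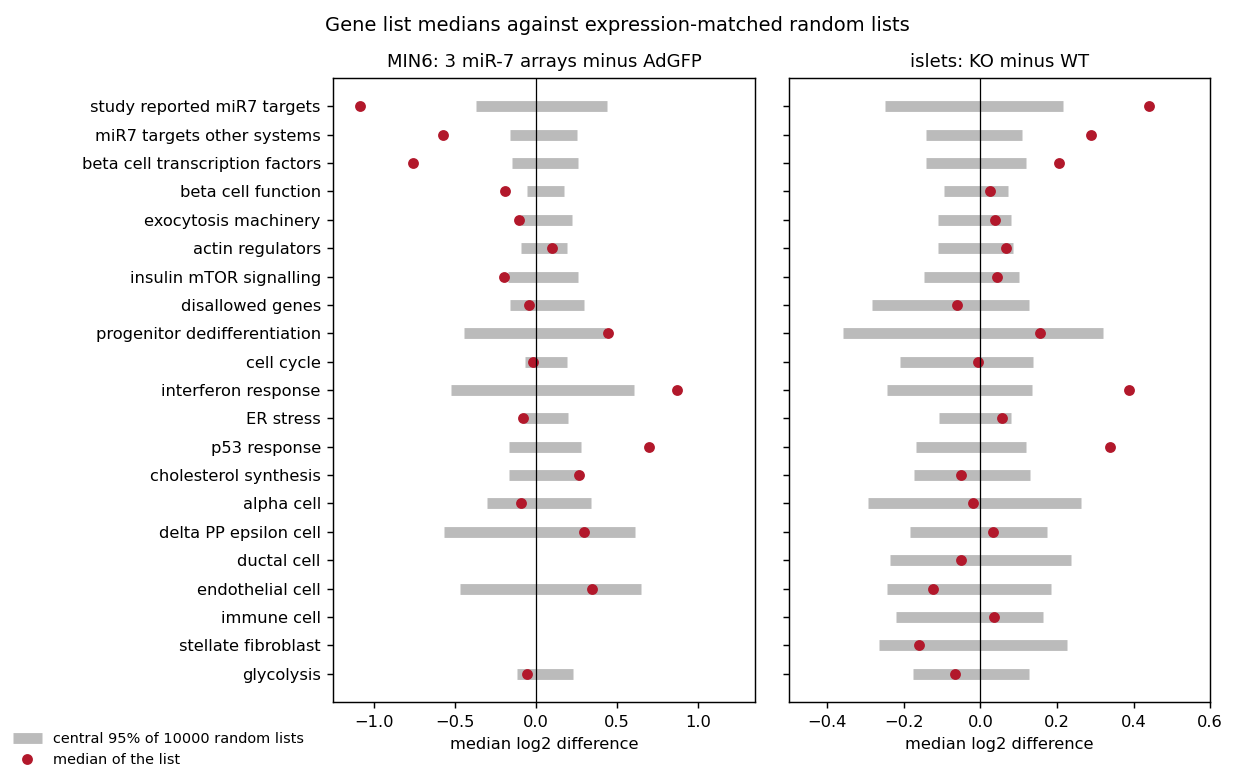
Median log2 difference of each gene list (points) for the 3 miR-7 arrays minus AdGFP in MIN6 (left) and KO minus WT islets (right), over the central 95% of 10000 expression-matched random lists (grey bars); lists with fewer than 3 measured genes are left out. Both lists of miR-7 targets are low in MIN6 (-1.08 and -0.57) and high in KO islets (0.44 and 0.29).

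Comparing both systems asks which genes move in opposite directions when miR-7 is raised and when miR-7a2 is deleted. Among the opposed genes, Tacr3 was at -3.13 with miR-7 and 2.49 higher in KO islets; the sterol enzyme gene Hsd17b7 was at -1.62 and 2.09, the glycine transporter gene Slc6a9 at -1.61 and 1.62, Cth at -2.34 and 1.43, Ttyh1 at -1.35 and 2.19, Rprml at -1.34 and 1.79 and Praf2 at -1.92 and 1.31. Pcdhb16 (-1.24, adjusted p = 0.113, and 1.42), the collagen gene Col6a3 (-1.30 and 1.22) and the DNA polymerase subunit gene Pole4 (-1.39 and 1.16) followed. In the other direction stood Pamr1 (1.73 with miR-7 and -1.58 in KO), the potassium channel gene Kcnk16 (1.43 and -1.35), Col8a1 (1.54 and -1.24), the integrin gene Itgb8 (1.26 and -1.24) and Lin7b (1.22 and -1.19). All of these except Pcdhb16 passed the pooled limma test in MIN6. Probe sets were chosen within each system, so the MIN6 and islet values of a gene can come from different probe sets.

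At a log2 size of 0.58, 103 genes were lower with miR-7 and higher in KO, against 32.8 for independent sets, and 98 were higher with miR-7 and lower in KO, against 31.7. Genes moving the same way in both numbered 17 (lower) and 18 (higher), against 32.0 and 32.5. At a size of 1 the opposed genes numbered 17 and 15, against 3.03 and 1.86, and those moving the same way 2 and 2. Across the 9781 genes Pearson's r was -0.268 and Spearman's rho -0.247; genes are not independent replicates, and AdGFP and both islet groups are single arrays.

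**Figure D4:**
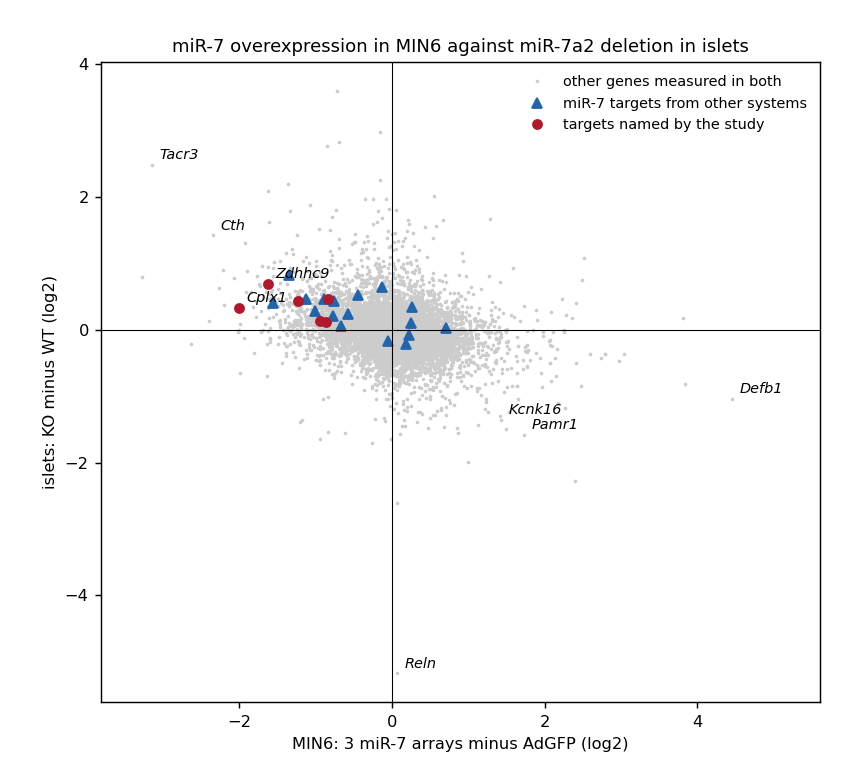
Log2 difference of the 3 miR-7 arrays minus AdGFP in MIN6 (horizontal axis) against KO minus WT islets (vertical axis), 1 point per gene measured in both; red circles are targets named by the study and blue triangles targets from other systems. Tacr3 lies at -3.13 and 2.49, Defb1 at 4.46 and -1.03.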

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

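The control probe sets, which take no part in the comparisons, differed between groups. 18S ribosomal RNA was 0.335 (log2) higher in KO than in WT islets. The hybridisation controls were 0.188 higher on the miR-7 arrays than on AdGFP on average, on all 3 arrays. Only controls higher in KO or on all 3 miR-7 arrays were flagged. The largest islet control difference went the other way, with spiked poly-A transcripts at -1.31 (KO minus WT). In MIN6, 18S ribosomal RNA stood at 14.0 on AdGFP, 13.6 on both AdmiR7a arrays and 13.9 on AdmiR7b. Of the tests in the paragraphs on patterns below, those on an unrelated AdGFP deviation, on p53 targets in islets, on strain segments away from the locus and on non-beta cells were chosen after the results were seen.

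Many genes differed between the lone AdGFP array and the 3 miR-7 arrays. The 3' minus 5' control differences argued against degraded RNA on the AdGFP array: it exceeded the highest miR-7 array by 0.00269 for actin and lay below it for Gapdh (-0.0497). In islets, which do not use that array, the miR-7 targets from other systems lay at percentile 100 of random lists in KO minus WT, and outside both target lists 85.04% of the 234 genes past 0.58 in both systems went opposite ways. Neither value has a spread over arrays, since genes are co-regulated and each islet group has 1 array, so a deviation of the AdGFP array unrelated to miR-7 and an effect of miR-7 cannot be told apart for these genes. Both stay open as well for the 2473 called genes that were under that size or not measured in islets.

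Of 14 p53 targets measured in MIN6, 6 rose and 1 fell with miR-7. The shift of the list's median did not hang on a few members or on the choice of probe set: the lower of the percentiles with averaged probe sets and without the 3 members that rose most was 99.1. An effect of the miR-7 level that also acts in islets would put the list below 0 in KO islets, where its median was 0.337, but with 1 array per group it stays open. A difference in virus dose or stress between the AdGFP culture and the others was not tested and stays open, as does an effect of miR-7 limited to MIN6 cells.

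KO and WT islets differed by large folds in single genes. A strain segment around the targeted locus may be set aside as the main source: 2.15% of the genes past a log2 size of 1 lay among the 100 measured genes on either side of it. Strain segments elsewhere remain a candidate explanation for part of the genes, since 64 had another such gene within 3 measured genes, against a median of 41 in shuffles, while the AdmiR7a genes of the MIN6 line gave 114 against 105. No large difference in the shares of endothelial, immune or stellate cells was seen: the largest median of these lists was 0.159 in size. All 5 measured stellate genes were lower in KO, as were 5 of 9 endothelial and 5 of 11 immune genes. Acinar and ductal cells were not part of that test, and a smaller difference stays open with 1 array per group. Variation between animals and loss of miR-7a2 itself stay open with 1 array per group. Mx1, whose alleles differ between laboratory strains, had no other such gene within 3 measured genes, nor had Reln, Fam107a or Tacr3. Fgg, Npy and Prr5l, and the opposed genes Col6a3, Pamr1 and Pole4, are among the 64 genes that did.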

How the results depend on the processing

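The alternatives were chosen before the data were examined, except single miR-7 arrays for list medians, camera with an array left out, the opposition without the 2 target lists, p53 targets without the 3 members that rose most and interferon genes without Mx1. No direction of a called result reversed. The pooled miR-7 count of 2715 genes stayed between 2570 and 3366 under the stricter filter, renormalization, centring (1501 higher and 1480 lower, against 1480 and 1235), other probe set choices and another prior. It was 981 with no filter, 4161 at an adjusted p under 0.1, and 0 to 0 with any miR-7 array left out, a design with 1 residual degree of freedom. The AdmiR7a count of 0 by limma became 350 with no filter, 1737 with a filter at 6, 2362 with renormalization, 2325 with centring, 967 with averaged probe sets and 2654 at an adjusted p under 0.1; the lowest adjusted p was 0.0667, so small shifts cross the threshold. Its count by size (452) was 761 over single probe sets. AdmiR7b against AdmiR7a by size gave 21 genes, and 35 to 37 with 1 AdmiR7a array. AdmiR7b by size (842) gave 557 with averaged probe sets, 1536 over single probe sets, 2417 at a size of 0.58 and 0 by limma with a borrowed spread. KO against WT (280) gave 423 with no filter, 134 with a filter at 6, 183 with averaged probe sets, 794 over single probe sets (573 higher, 221 lower) and 933 at 0.58. Of the lists, 6 passed camera, 0 with an estimated correlation, and 5 to 8 with an array left out (p53 targets missed without AdmiR7a replicate 2, adjusted p = 0.0532); fry gave 8, with p53 targets missing (adjusted p = 0.0699) and cholesterol, interferon and endothelial genes added. The correlation of MIN6 and islet differences was -0.283 with a filter at 6, -0.193 with no filter and -0.253 with AdmiR7b alone; the 103 opposed genes became 17 at a size of 1. Of 147 named genes tested in MIN6, 92 passed; 69 of these missed the threshold with no filter, 5 with averaged probe sets and all 92 with any array left out. Of 158 named islet genes with averaged probe sets, 46 moved. Beyond thresholds and genes tested, the cause was not tested. Seed sites were not run. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Genes near the background limit the folds.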

Other observations

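The test in this part on prolactin signalling was planned before its values were seen; it asks about a known side effect of some Cre lines, and the labels do not name the Cre driver. Some markers of other cell types were measured in MIN6 cells. The alpha-cell hormone gene Gcg fell by 0.53 ± 0.11 with miR-7 (adjusted p = 0.0423) from a level of 13.4 on AdGFP, 1 of 5 alpha-cell genes that passed, and 1 adjusted over the list alone. The retinol-binding protein gene Rbp4 rose by 0.62, 1 of 4 delta, PP and epsilon genes. Of 4 endothelial genes 2 rose, among them Esam by 0.79, and of 2 ductal genes the keratin gene Krt18 rose by 0.65. The complement gene C1qa fell by 1.12 and Vim fell by 0.73, each the 1 measured gene of the immune and stellate lists; Vim alone of this pair was near the background (3.75 with AdmiR7a). No acinar or adipocyte gene was measured in MIN6 (0 and 0); in islets the elastase gene Cela1 was at 0.02 and the fatty acid-binding protein gene Fabp4 at -0.15.

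Prolactin receptor signalling in the KO islets, as a Cre transgene that makes growth hormone could give, was tested on its responsive genes. Of the 4 genes planned, Tph1 was below the expression filter in islets. The other 3 differed by under 0.5 (log2) or were lower in KO: Cish was at -0.31, Socs2 at 0.42, and Tph2, near the background (4.18 in KO, 4.57 in WT), at -0.39.

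Genes within 100 measured genes of the miR-7a2 locus and past a log2 size of 1 in islets were Plekhb1 (-1.79), Lin7b (-1.19), Ube3a (1.0), Tm6sf1 (1.03), Tenm4 (1.32) and Hdgfl3 (1.39). Their share there, 3% of 200 genes, differed little from the 2.64% elsewhere (Fisher's exact test, two-sided p = 0.656).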
